A study of Mus musculus with 14 samples.

How the data were processed

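Bone marrow-derived macrophages were grown from FVB/Hsd mice in medium with L929-conditioned supernatant, infected with retroviruses that carried a short hairpin RNA against Wdr82, against Menin or a scrambled sequence, and selected with puromycin, per the labels' protocols. The series holds 14 samples of ribosomal RNA-depleted total RNA or of newly made RNA labelled with 4-thiouridine, from untreated cells or from cells given lipopolysaccharide at 10 ng/ml for 45 min. Count tables exist for 4 of them, all untreated total RNA: scrambled 1, scrambled 2 and 1 library for each of the Wdr82 hairpins sh1137 and sh830. The other 10 samples, among them all Menin and 4-thiouridine samples, were not analysed here. Total RNA was isolated with RNeasy columns and DNase I, depleted with Ribo-Zero and made into strand-marked libraries with a TruSeq kit, per the labels' protocols.

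The authors deposited raw read counts per gene over exon intervals and, separately, over intron intervals, without normalization. The unit was read from the values, which are whole numbers whose totals differ between libraries. The submitters' processing notes name TopHat 1.3.1, Cufflinks 2.1.1, Cuffdiff 2.1.1, SICER and the mm9 build. They do not state which tool counted the reads or whether it used the strand, so reads of overlapping genes, of antisense neighbours and of near-identical copies could have been shared between features. The authors' deposited annotation gives other data besides the counts: mm9 coordinates of 21761 genes from the UCSC known genes and of regions without a strand. The source field of the regions names a SICER comparison of hairpin with vector (LMP) libraries of untreated cells. They were therefore chosen on a knockdown comparison, and their direction is not independent evidence. Of the regions, 405 overlap an annotated exon and 702 do not. Gene identifiers were matched to symbols by identifier, and 21615 of 21761 had a symbol. No genome sequence was at hand, so GC content was not checked.

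Exon counts of genes and regions were fitted together in edgeR 4.0.16 (R 4.3.3) with TMM factors from the genes, the filterByExpr filter, an intercept and a group term, and quasi-likelihood F-tests. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Intron counts were fitted in the same way with factors of their own. Intron against exon change was the interaction of group and interval type over the exon and intron counts of the same genes, with a term for each library. Each group has 2 libraries, and the knockdown libraries differ in hairpin, so hairpin differences are part of their spread. Gene lists and region classes were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on voom values, beside camera with an estimated correlation and fry. Both of the latter were alternatives. Values of these tests and medians by region class or gene length are from fits with the group term alone unless stated, and list medians and called members are from the fit with the library term described below. Region classes were fixed by place: overlapping a gene, within 5 kb of a gene start, within 20 kb of a gene end, or intergenic. Regions were also classed by the start (TSS) or end (TES) of the gene in their names. An exact permutation of 2 against 2 libraries cannot go below p = 0.33, so shares of counts are given as values.

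The designs, gene lists and the rule for named genes were fixed before the data were examined. One term was added after the data were examined. Scrambled 1 and sh1137 had a high intron share of counts, scrambled 2 and sh830 a low one, and a term for this split (the library term) was added to each fit. The split is a measured difference between libraries and not a study group, and the labels give no batch. The fit with it has 1 residual degree of freedom and rests on the moderation of the spread across genes. A term for the crossed split (scrambled 1 with sh830) was fitted for comparison and leaves the first split in the residual spread. The fit with the group term alone passed 0 features, so the naming rule was applied to the fit with the library term, a choice made after the data were examined. Words such as rose and fell refer to an adjusted p under 0.05 in that fit.

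The naming rule took Wdr82; the 12 largest exon rises and 12 largest falls past the threshold with a mean of at least 1 count scaled per 1e6 library counts (CPM) and both knockdown libraries on the same side of both scrambled libraries; 8 each way for introns; 4 regions each way; the 6 largest each way for intron against exon; and the 2 members with the smallest p in each direction of each list with a called member. Names of unnamed gene models, small nucleolar RNAs, microRNAs and pseudogenes were passed over. Pseudogenes were at first recognised by annotated type, which dropped Mx1; this was changed to recognition by name after the first selection was seen, and Mx1 then took the place of Fcgr1 among the 12 exon falls.

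The 24 lists covered Wdr82 complexes, the Menin/MLL complex, interferon-stimulated genes, LPS-inducible inflammatory genes, macrophage identity, the cell cycle, p53 targets, the unfolded protein and integrated stress response, cholesterol synthesis, 3′ end processing and termination factors, the nuclear exosome, replication-dependent histones, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation (OXPHOS) genes, small nucleolar RNA hosts, and markers of neutrophils, dendritic cells, stromal cells, lymphocytes, erythroid cells and megakaryocytes, mast cells with basophils and eosinophils, progenitors and osteoclasts. The list of mitochondrially encoded genes matched 0 genes in the annotation. In total 22 lists had at least 5 tested members among exon counts.

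Depth ranged over counts in exons of genes from 34787556 (sh1137) to 43372731 (sh830), and over intron counts from 7294679 (scrambled 2) to 27506915 (sh1137). Where both scrambled libraries held 0 counts, a lower bound of the fold was taken from 3 counts over the group. Where they held 1 to 3 counts together, the ratio is given with its exact 95% binomial interval. Shares of counts carry 95% Wilson intervals. All such intervals and bounds cover counting error only. Values per group are means with the SD of 2 libraries, and log2 fold changes carry the standard error of the fit.

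Alternatives were DESeq2 1.42.0 with its own size factors, those size factors in edgeR, no low-count filter, a filter of 10 counts in every library of one group, a test against a fold of 1.5, factors from all features, exon factors for intron counts, narrower class distances, another length measure, and each library left out in turn. All were repeated for the fit with the library term except leaving out a library, which leaves 0 residual degrees of freedom. The fits were tested on simulated data, with 200 changed genes each. The simulated spread and split were taken from the fit with the library term, and genes were drawn independently. The simulation therefore favours that term and does not tell whether it suits the real data. With the observed split simulated, the exon fit with the group term alone recovered 0% of the changed genes at every fold size. With the library term it recovered 100%, 72%, 86% and 98% of the genes changed by -2, -1, 1 and 2 log2 units, among 14562 genes and regions. The share of false calls was 5.82% for exon counts, 11.9% for intron counts (12058 genes) and 16.0% for intron against exon (11772 genes), so all 3 exceeded the nominal 5%. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 handled the tables and figures.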

Results

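Macrophages grown from mouse bone marrow carried retroviral hairpins against Wdr82 or a scrambled control, and the untreated cells' ribosomal RNA-depleted total RNA was sequenced. Wdr82 is a subunit of the SET1 histone methyltransferase complexes and of the PTW/PP1 phosphatase complex. There were 2 scrambled libraries and 2 knockdown libraries, 1 for each of the hairpins sh1137 and sh830. Counts in the exons of genes were 40074419 and 42635790 in scrambled 1 and 2, 34787556 with sh1137 and 43372731 with sh830. Intron counts were 27189233 and 7294679 in scrambled 1 and 2, 27506915 with sh1137 and 7793113 with sh830. Introns thus took 40.4% and 14.6% of the exon plus intron counts in the scrambled libraries and 44.2% and 15.2% with sh1137 and sh830 (95% Wilson intervals 40.41 to 40.43, 14.6 to 14.62, 44.14 to 44.17 and 15.22 to 15.24%). The annotated non-gene regions, of which 405 overlap an exon and 702 do not, held 269392 and 170016 counts in the scrambled libraries, 885842 with sh1137 and 398461 with sh830.

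The knockdown was visible in both hairpin libraries. Wdr82 (identifier 77305; mm9 chromosome 9, 106073260 to 106094037, plus strand; its span also holds Mirlet7g) had 100 and 144 CPM over its exons in scrambled 1 and 2, against 25.1 CPM with sh1137 and 40.7 CPM with sh830. The group means were 122 ± 31.0 CPM and 32.9 ± 11.1 CPM (SD, n = 2 each). With the library term Wdr82 fell by 1.91 ± 0.094 on the log2 scale (adjusted p = 0.0022, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With the group term alone the log2 fold change was -1.89 ± 0.35 and the adjusted p was 0.44 in edgeR. It passed there in DESeq2 (-1.90, adjusted p = 0.00051), without scrambled 1 (-2.14, adjusted p = 0.0016 in edgeR) and without sh830 (-2.28, adjusted p = 0.0076 in edgeR), and did not without scrambled 2 (-1.58, adjusted p = 0.22 in edgeR) or sh1137 (-1.59, adjusted p = 0.072 in edgeR). The intron counts of Wdr82 had a log2 fold change of -0.35 ± 0.10 (adjusted p = 0.079 in edgeR with the library term).

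**Figure D1:**
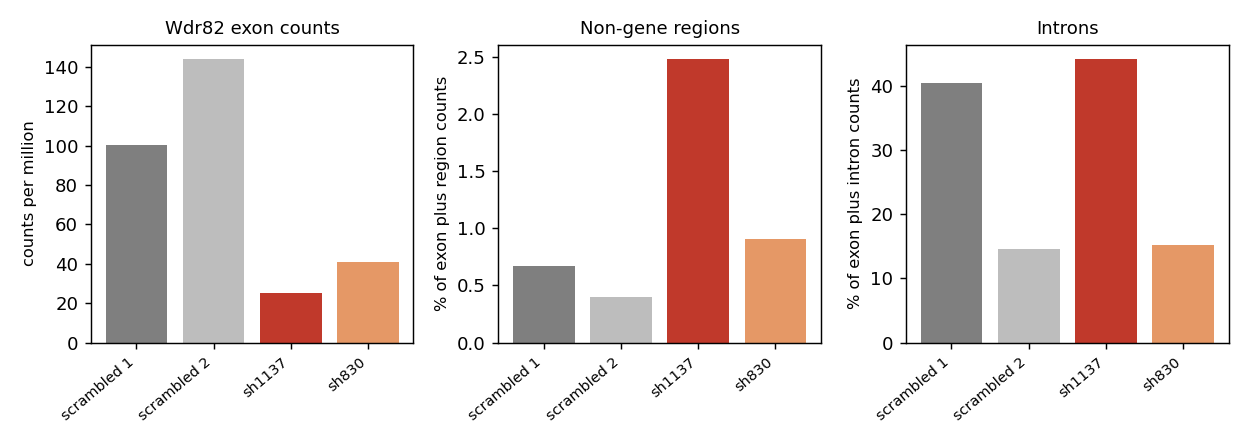
Bars give, for each of the 4 libraries, the exon counts of Wdr82 in CPM, the counts in non-gene regions as a percent of exon plus region counts, and the intron counts as a percent of exon plus intron counts. Wdr82 was lower and the region share higher with both hairpins. The intron share mainly followed the split of the libraries (40.4% and 44.2% against 14.6% and 15.2%), and on each side of the split it was higher with the hairpin.

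The series title concerns early termination of transcription at cis-regulatory elements, and the first comparison asks whether RNA from non-gene regions changed with Wdr82 knockdown. It was higher almost throughout. The regions took 0.668% and 0.397% of the counts in gene exons plus regions in scrambled 1 and 2, and 2.48% and 0.910% with sh1137 and sh830 (95% Wilson intervals 0.6652 to 0.6703, 0.3953 to 0.3991, 2.478 to 2.488 and 0.9075 to 0.9131%). Of 1070 regions tested, 584 rose and 0 fell with the library term, and 387 of those that rose overlap no annotated exon. With the group term alone the median log2 fold change over all tested regions was 1.42, and 98.3% of the values were positive. Regions were chosen by the authors from a hairpin against vector comparison, so neither these counts nor this share is independent evidence of direction.

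The Fc receptor locus on mm9 chromosome 1 held one of the 4 named regions and a run of neighbours that rose with it. The region named for the start of Fcgr2b (172906500 to 172922499, overlapping an exon at that gene's start) went from 0.372 ± 0.077 CPM to 26 ± 1.4 CPM (SD, n = 2 each), a log2 fold change of 6.12 ± 0.22 (adjusted p = 0.0020 in edgeR). Fcgr2b itself, the inhibitory receptor for IgG, rose from 83.6 ± 18.5 CPM to 168 ± 54.0 CPM, by 0.99 ± 0.095 log2 units (adjusted p = 0.0073 in edgeR). The smaller regions named for the end of Fcgr2b rose by 3.22 and 2.1 log2 units. Farther along the minus strand, the region at the start of Fcrla rose by 5.03 and the region at the end of Fcrlb by 3.97 log2 units (adjusted p from 0.0069 to 0.020 for these 4 regions in edgeR). Fcrla and Fcrlb, which encode Fc receptor-like proteins described in B cells, rose as well and are given with the exon counts. As neighbours could share reads, the regions and genes of this locus are not separate evidence.

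**Figure D2:**
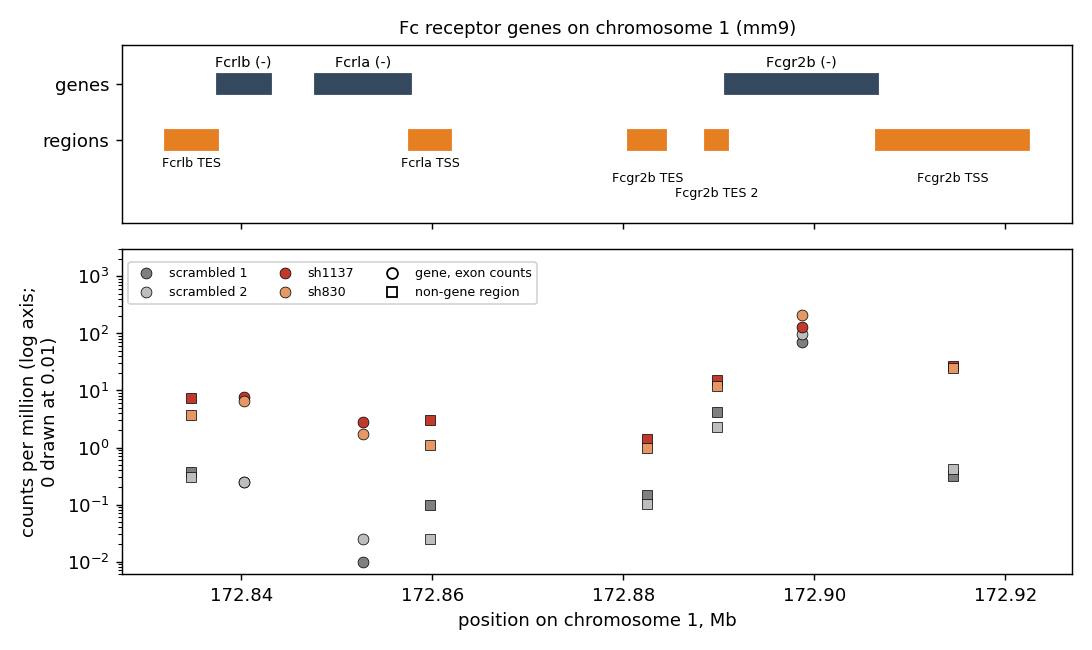
Genes and non-gene regions on mm9 chromosome 1 are drawn to scale by position in Mb, with CPM in the 4 libraries on a log axis underneath (0 drawn at 0.01). Only Fcgr2b, Fcrla, Fcrlb and the regions named for them are drawn. These 3 genes and 5 regions were higher in both hairpin libraries than in both scrambled libraries, from 0.372 to 26 CPM on average for the region at the start of Fcgr2b.

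The other named regions lie far upstream of the genes whose names they carry. The region named for the start of Pgrmc2 (mm9 chromosome 3, 41046500 to 41050499, 159532 bp upstream) held 2 and 0 counts in the scrambled libraries and 105 and 53 with sh1137 and sh830, a ratio of 80.1 (exact 95% binomial interval 21.8 to 667). The region Lrp12 TSS 2 (chromosome 15, 39887500 to 39894999, 112197 bp upstream of Lrp12) held 4 and 0 counts against 197 and 23. The region Thbs1 TSS 7 (chromosome 2, 117865500 to 117874999) held 4 and 0 counts against 174 and 42. It is 1 of 7 regions that span 120 kb upstream of Thbs1, which encodes the matrix protein thrombospondin 1, and all 7 rose, by 2.13 to 5.84 log2 units (adjusted p from 0.0043 to 0.029 in edgeR). These neighbours were looked up after Thbs1 TSS 7 had been named by the rule. Thbs1 itself had a log2 fold change of 1.46 ± 0.39 (adjusted p = 0.060 in edgeR), with 38.6 CPM for sh1137 and 177 CPM for sh830 against 25.5 and 36.4 CPM in the scrambled libraries.

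By place, the median log2 fold change with the group term alone was 2.16 for 268 intergenic regions, 1.52 for 198 regions within 5 kb of a gene start, 1.28 for 176 regions within 20 kb of a gene end and 1.13 for 428 regions that overlap a gene. Region medians with the library term also went from 4.46 in the sparsest to 0.734 in the densest of 20 classes of counts per kb in the scrambled libraries. The scrambled counts that set these classes are also the base of the change, so a trend of this direction is partly built in. Introns, which were not chosen for a rise, went from 0.87 to 0.0057 in the same classes. The order by place was not adjusted for this count density or for the choice of regions. Regions named for a start had a median of 1.63 (353 of 577 rose) and those named for an end 1.19 (231 of 493 rose). The excess was larger for sh1137 over scrambled 1 (median 1.63 over all regions) than for sh830 over scrambled 2 (1.06), and scrambled 1 lay above scrambled 2 by 0.56. All 7 class tests passed in camera with a preset correlation (p from 2.1e-53 to 3.9e-22 for the classes, 6.9e-54 for all regions). None passed with an estimated correlation (p = 0.17 for all regions, 0.165 to 0.252 for the classes) or in fry (0.191, and 0.143 to 0.265). With the group term alone, edgeR called 0 regions in either direction, with 419 higher and 0 lower at an unadjusted p under 0.05, and DESeq2 called 283 higher and 0 lower. Without scrambled 1, scrambled 2, sh1137 or sh830 that edgeR fit called 190, 23, 79 and 364 higher and 0 lower.

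**Figure D3:**
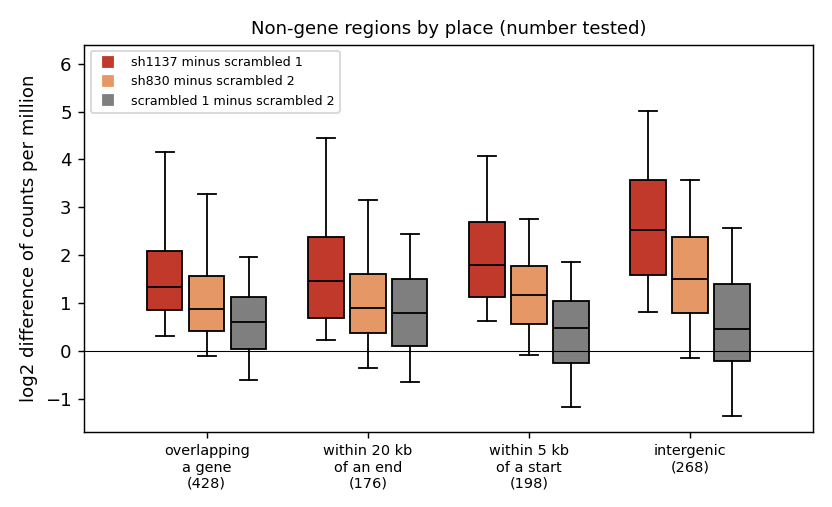
Boxes give the quartiles (line, median) of the log2 differences in CPM of non-gene regions by place, for sh1137 minus scrambled 1, sh830 minus scrambled 2 and scrambled 1 minus scrambled 2; whiskers reach the 5th and 95th percentiles. Both hairpin differences have medians above the difference of the scrambled libraries in each class, and intergenic regions have the largest medians (2.52 for sh1137 and 1.5 for sh830).

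Exon counts of genes ask which mature and partly processed transcripts changed. Genes scarcely detected in the scrambled libraries, such as Cd6, Fcrla and Ccr3, rose by the largest folds, and interferon-stimulated genes such as Oasl1 and Mx1 were among the largest falls. Of 13884 genes tested, 841 rose and 1081 fell with the library term. Among those that rose, 199 had under 1 CPM on average in the scrambled libraries and 421 had at least 10 CPM. A ranking by fold favours genes with few counts in the scrambled libraries. Ppp1r10 (PNUTS), the scaffold of the PTW/PP1 complex that holds Wdr82, rose from 73.1 ± 1.1 CPM to 263 ± 8.6 CPM (SD, n = 2 each), by 1.85 ± 0.088 log2 units (adjusted p = 0.0020 in edgeR).

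The 12 largest rises included surface receptors and signalling genes of other tissues. Cd6 (identifier 12511; chromosome 19, 10863829 to 10904548), a T-cell glycoprotein, had 0 exon counts in both scrambled libraries and 115 and 77 with sh1137 and sh830, at least 64.9-fold higher. Fcrla (98752; chromosome 1, 172847725 to 172857714) had 0 and 1 counts against 107 and 73, a ratio of 182 (exact 95% binomial interval 32.3 to 7246). Fcrlb rose by 4.82 ± 0.32 log2 units, from 0.248 ± 0.0045 to 7.08 ± 0.79 CPM. Ccr3, the eotaxin receptor of eosinophils, rose by 4.53 ± 0.34, from 0.608 ± 0.13 to 14.5 ± 4.7 CPM. Gnat3, the taste G protein subunit gustducin, rose by 4.28 ± 0.28, from 0.734 ± 0.35 to 13.9 ± 1.5 CPM. Asgr2, a subunit of the hepatic asialoglycoprotein receptor, rose by 4.23 ± 0.37, from 0.573 ± 0.40 to 10.1 ± 1.5 CPM. The kallikrein gene Klk1b1 (5.91), the guanylate cyclase gene Gucy2g (4.76), Cracdl (4.63), the inositol phosphate kinase gene Ip6k3 (4.61), the mechanosensitive channel gene Piezo2 (4.28) and the leukocyte receptor gene Cd300c (4.15) made up the rest. Adjusted p-values for these 12 genes lay between 0.0046 and 0.014 in edgeR's quasi-likelihood test. Klk1b1 has near-identical paralogs, so its counts are uncertain. The span of Snora19 overlaps Gucy2g, but spans run from the first to the last annotated base on a chromosome and strand. Copies of Snora19 far apart would appear as 1 span, so this overlap is uncertain.

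The 12 largest falls were led by Ifi27l2a, an interferon-induced gene whose span overlaps Ifi27, at -2.76 ± 0.17 log2 units (83.2 and 245 CPM in the scrambled libraries, 9.72 and 44.6 CPM with sh1137 and sh830). Oasl1 (-2.38), Oas1g (-1.95), Mx1 (-1.69), Rtp4 (-1.67) and Isg15 (-1.51) are also induced by interferon. Camk2b, a subunit of a calcium/calmodulin-dependent kinase, fell by 2.18 ± 0.096, from 80.7 ± 52.5 to 17.6 ± 10.8 CPM. Cspg4, a cell surface proteoglycan, fell by 2.05 ± 0.16, from 22.8 ± 2.5 to 5.46 ± 0.25 CPM. Ly9, a receptor of the SLAM family, fell by 1.6 ± 0.090, from 121 ± 4.5 to 39.9 ± 4.4 CPM. The B-cell receptor component Cd79b (-1.57), the aldo-keto reductase gene Akr1c13 (-1.52) and Wdr82 completed the set. Adjusted p-values for the 12 lay between 0.0020 and 0.034 in edgeR. The Oas genes are a family of close paralogs, so reads could be shared among them.

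With the group term alone, edgeR called 0 of 13884 genes, with 437 higher and 209 lower at an unadjusted p under 0.05, and DESeq2 called 153 higher and 23 lower. Without scrambled 1, scrambled 2, sh1137 or sh830 that edgeR fit called 62, 13, 190 and 94 genes higher and 15, 1, 16 and 28 lower.

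**Figure D4:**
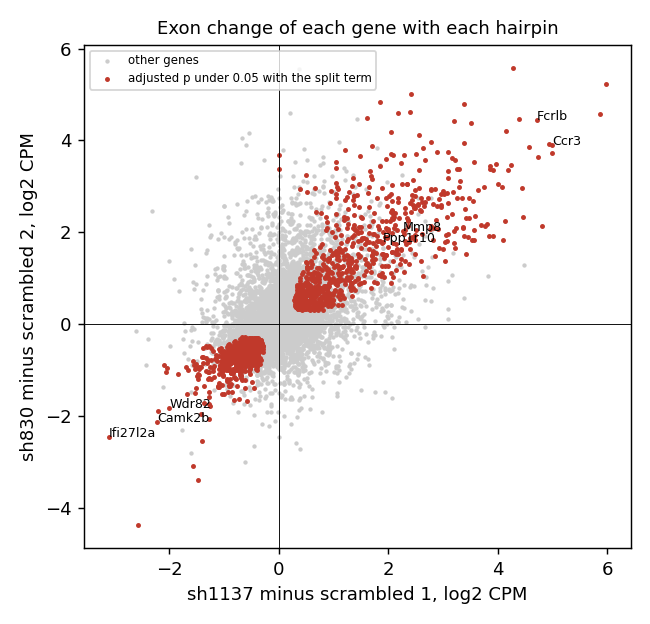
Each point is a gene, with the log2 difference in CPM of sh1137 minus scrambled 1 on the horizontal and of sh830 minus scrambled 2 on the vertical axis; red points passed the test with the library term. All 1922 called genes have the same sign in both differences, which the construction of that test favours.

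Interferon-stimulated and cell cycle genes had medians below 0 with the knockdown. For comparison with the list counts given here and below, 841 of all 13884 tested genes rose and 1081 fell. The list counts were not tested against these. Of 50 interferon-stimulated genes, 14 fell and 0 rose (22 and 1 adjusted over the list alone), with a median log2 fold change of -0.43. Oas2 fell from 91.5 ± 42.7 to 34.5 ± 23.5 CPM (-1.51) and Mx1 from 31.6 ± 6.9 to 10.3 ± 4.9 CPM (-1.69), while Gbp2 (0.45) and Gbp3 (0.42), guanylate-binding proteins with close paralogs, did not pass. Of 48 cell cycle genes, 32 fell and 0 rose (42 and 0 adjusted over the list alone), with a median of -0.52. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, fell from 67.1 ± 15.7 to 29.0 ± 8.2 CPM (-1.22). Cdc20, an activator of the anaphase-promoting complex, fell from 87.3 ± 16.4 to 44.8 ± 8.2 CPM (-0.96; Elovl1 overlaps its span), and E2f2 (0.01) did not pass. Both lists passed in camera (adjusted p = 1.1e-09 and 2.3e-19), and both had an adjusted p = 0.53 with an estimated correlation. Scrambled 1 lay below scrambled 2 in both lists (medians of -0.15 and -0.31). The interferon-stimulated genes had a median of -0.22 for sh1137 over scrambled 1 and -0.63 for sh830 over scrambled 2, and the cell cycle genes -0.53 and -0.51.

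Replication-dependent histone genes fell in 34 of 60 members and rose in 1 (47 and 1 adjusted over the list alone), with a median of -0.69. H4c3 fell by 1.06, from 113 ± 92.7 to 53 ± 42.1 CPM, H2bc23 (-4.41) went from 44.1 ± 62.1 to 2.09 ± 2.9 CPM, and H2bc21 rose by 1.63, from 4.17 ± 0.78 to 12.9 ± 2.3 CPM; H2ac18 (0.73) did not pass. Without scrambled 2 the values of H4c3 and H2bc23 turned positive (0.19 and 3.09) and did not pass. Histone copies are near-identical, so single members are uncertain, and scrambled 1 lay below scrambled 2 by a median of 1.57 log2 units in this list (-1.57). Cytosolic ribosomal protein genes fell in 7 of 82 members (5 adjusted over the list alone), near the share over all tested genes (1081 of 13884). OXPHOS genes fell in 19 of 76 (28 adjusted over the list alone). None rose in either list, and the medians were -0.22 and -0.28. Rpl22l1 (-0.61, but 0.27 and not past the threshold without scrambled 2), Rpl36a (-0.65), Uqcrq (-0.96) and Ndufa12 (-0.83) fell, and Rplp2 (0.08), Rpl39l (0.81), Cox7a2l (0.12) and Cox6a2 (1.45) did not pass. Scrambled 1 minus scrambled 2 had medians of -1.06 and -0.92 in these lists. The ribosomal list had a median of -0.35 for sh1137 over scrambled 1 and -0.13 for sh830 over scrambled 2. The 3 lists passed in camera (adjusted p = 0.00011, 0.0094 and 0.0015), each with an adjusted p = 0.78 with an estimated correlation. The direction turned upward without scrambled 2 (adjusted p = 0.087, 1.7e-05 and 0.0078 in camera) and without sh1137 (0.33, 4.3e-05 and 0.11).

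Some genes of cholesterol synthesis and of the stress response fell. Of 24 cholesterol synthesis genes 7 fell and 0 rose (14 and 0 adjusted over the list alone; median -0.67), among them Sqle (75.3 ± 15.6 to 42.5 ± 3.0 CPM, -0.81) and Hsd17b7 (-0.67). Scrambled 1 lay below scrambled 2 in this list (median -0.60), and the median was -0.28 for sh1137 over scrambled 1 and -0.97 for sh830 over scrambled 2. Of 33 genes of the unfolded protein and integrated stress response, 12 fell and 2 rose (16 and 4 adjusted over the list alone; median -0.28, mean -0.18). Scrambled 1 lay below scrambled 2 here too (median -0.29), and the median was -0.32 for sh1137 over scrambled 1 and -0.27 for sh830 over scrambled 2. The amino acid transporter gene Slc7a5 (-1.18) and the serine synthesis gene Psat1 (-0.91) fell. The cystine transporter gene Slc7a11 rose from 15.2 ± 3.9 to 76.6 ± 37.5 CPM (2.26), and Vldlr rose by 2.76 from 0.0750 ± 0.071 CPM. The span of Snora19 also overlaps Vldlr, which is uncertain for the same reason as for Gucy2g. Both lists passed in camera (adjusted p = 6.3e-10 and 0.00074), with an adjusted p = 0.53 and 0.57 with an estimated correlation. The stress list did not pass in camera without scrambled 2 (adjusted p = 0.18) or without sh1137 (0.11).

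Some factors that act near Wdr82 in transcription changed, in both directions, while most did not pass. Wdr82 itself, the target of the hairpins, is counted among them. Over all 13884 tested genes 841 rose and 1081 fell. In the list of Wdr82 complexes, Ppp1r10 and Zc3h4 rose and Wdr82 and Hcfc1 fell, of 16 members (2 rose and 3 fell adjusted over the list alone). Zc3h4, the zinc finger partner of Wdr82, went from 95.9 ± 20.1 to 168 ± 70.4 CPM (0.76), and Hcfc1, a host cell factor, from 321 ± 53.1 to 228 ± 39.2 CPM (-0.50). Of 45 3′ end processing and termination factors, 5 fell and 1 rose (3 and 0 adjusted over the list alone; median -0.16), with Cpsf3 (-0.55) and Cstf2 (-0.53) lower and the Integrator subunit gene Ints6 (0.45) higher, while Ints3 (0.55) did not pass. Of 24 nuclear exosome genes, 3 fell (0 adjusted over the list alone; median -0.28), among them Exosc8 (-0.55) and Tent4a (-0.51), while Rbm26 (0.15) and Zfc3h1 (0.06) did not pass. The last 2 lists passed in camera (adjusted p = 0.0044 and 0.00018), each with an adjusted p = 0.51 with an estimated correlation. The 3′ end list did not pass in camera without scrambled 1 (adjusted p = 0.090), scrambled 2 (0.054) or sh830 (0.15). The Wdr82 complexes did not pass in camera (adjusted p = 0.34). Neither the 9 genes of the Menin/MLL complex (0.81) nor the 14 small nucleolar RNA hosts (0.53) passed, with 0 members called in edgeR by either adjustment. The Menin/MLL complex passed in camera as higher without scrambled 1 (adjusted p = 0.0057) or sh830 (0.039) and as lower without scrambled 2 (0.027).

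Macrophage genes changed in both directions. Of 46 macrophage identity genes 13 fell and 4 rose (16 and 6 adjusted over the list alone; median -0.09). Fcgr1, the high-affinity IgG receptor, fell from 133 ± 18.3 to 46.6 ± 7.1 CPM (-1.51), and Cd68, a lysosomal glycoprotein, from 799 ± 204 to 417 ± 105 CPM (-0.94). Ctsl, a lysosomal protease, rose from 253 ± 1.9 to 415 ± 20.2 CPM (0.71), as did Fcgr2b. The list did not pass in camera (adjusted p = 0.090), and it passed as lower without scrambled 1 (adjusted p = 0.0011) and without sh830 (8.1e-05). Of 50 lipopolysaccharide (LPS)-inducible inflammatory genes tested in these untreated cells, 8 rose and 6 fell (14 and 9 adjusted over the list alone; median 0.32). The chemokine gene Cxcl3 rose from 0.433 ± 0.0097 to 6.00 ± 1.5 CPM (3.76) and Ier3 from 32.1 ± 2.6 to 78.0 ± 10.9 CPM (1.28), while the chemokine gene Ccl7 (-1.27) and the kinase gene Plk2 (-0.72) fell. This list passed in camera as higher (adjusted p = 0.023; adjusted p = 0.73 with an estimated correlation; medians of 0.086 for sh1137 over scrambled 1 and 0.29 for sh830 over scrambled 2), though not without scrambled 1 (0.54) or sh830 (0.94). Of 26 p53 targets, Trp53inp1 rose (1.05) and Ckap2 fell (-0.59), while Btg2 (0.48) and Rps27l (-0.33) did not pass. Adjusted over the list alone, 1 rose and 1 fell. The list passed in camera (adjusted p = 0.018; adjusted p = 0.53 with an estimated correlation; median 0.17), though not without scrambled 1 (0.82) or sh830 (0.84).

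Some markers of other cells that marrow cultures could hold rose, while most did not pass. Of 21 dendritic cell and antigen presentation markers 8 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.51). Cd74, the invariant chain of class II molecules, went from 105 ± 32 to 183 ± 86.9 CPM (0.75) and the actin-bundling gene Fscn1 from 0.851 ± 1.0 to 6.05 ± 7.8 CPM (2.62, but -0.61 and not past the threshold without sh830), while the near-identical H2-DMb1 (-0.55) and H2-DMb2 (-0.25) did not pass. Of 19 stromal and fibroblast markers 9 rose and 0 fell (10 and 0 adjusted over the list alone; median 1.32). Pdgfrb, a growth factor receptor, went from 9.11 ± 0.67 to 39.8 ± 3.6 CPM (2.13), and the collagen gene Col1a1 had 0.0978 and 9.26 CPM in scrambled 1 and 2 against 0.774 and 53.3 CPM with sh1137 and sh830 (2.58, but -2.61 and not past the threshold without sh830). Tagln (-0.16) and Bgn (-0.10) did not pass. Col5a2, the most abundant marker with sh830, had 0.196 and 16.1 CPM in the scrambled libraries against 0.721 and 64.3 CPM with sh1137 and sh830 (1.98). In this list scrambled 1 lay below scrambled 2 by a median of -4.18 log2 units. Both lists passed in camera (adjusted p = 0.0015 and 0.0044), with an adjusted p = 0.53 and 0.78 with an estimated correlation. The stromal list turned lower without scrambled 1 (adjusted p = 0.083) and without sh830 (0.74). The dendritic list did not pass in camera without sh1137 (adjusted p = 0.065).

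Of 9 osteoclast markers 3 rose and 0 fell (4 and 1 adjusted over the list alone; median 0.82), with the protease gene Ctsk going from 1.71 ± 0.24 to 12.2 ± 7.2 CPM (2.71) and Atp6v0d2, a proton pump subunit, from 2.08 ± 1.2 to 9.71 ± 1.4 CPM (2.33), while Tnfrsf11a (-0.34) did not pass. Of 20 neutrophil and granulocyte precursor markers, Mmp8 (31.7 ± 8.0 to 144 ± 52.2 CPM, 2.16) and Mmp9 (9.71 ± 6.5 to 52.7 ± 18 CPM, 2.53; also in the osteoclast list) rose, and Chil3 (-0.89) and S100a9 (-0.92) did not pass. Of 9 erythroid and megakaryocyte markers, Ppbp (0.702 ± 0.39 to 7.51 ± 1.6 CPM, 3.48) and Vwf (0.56) rose, and Tfrc (-0.12) did not pass. Adjusted over the list alone, 2 neutrophil and 3 erythroid and megakaryocyte markers rose and 0 fell. Of 11 lymphocyte markers, the kinase gene Lck rose (1.87), Cd79b and Il7r (-0.82) fell, and Ms4a1 (2.90) did not pass. Of 10 progenitor markers Sox4 rose (1.53) and Ly6a fell (-1.28), while Myb (0.92) and Lyl1 (-0.39) did not pass. Adjusted over the list alone, 1 lymphocyte marker rose and 2 fell, and 1 progenitor marker rose and 2 fell. Of 4 mast cell, basophil and eosinophil markers, too few for a list test, Ccr3 rose, and Siglecf (1.85), Kit (-0.71) and Il5ra (-0.11) did not pass; adjusted over the list alone 2 rose. In camera the osteoclast (adjusted p = 0.0015) and erythroid and megakaryocyte lists (0.034) passed, with an adjusted p = 0.51 and 0.75 with an estimated correlation. The neutrophil (0.76), lymphocyte (0.71) and progenitor (0.63) lists did not. Scrambled 1 minus scrambled 2 had a median of 1.11 in the erythroid and megakaryocyte list, against a median change of 0.44. In the osteoclast list it was -0.15. The erythroid and megakaryocyte list did not pass without scrambled 2 (adjusted p = 0.86 in camera) or without sh1137 (0.74). The neutrophil list passed as higher without scrambled 1 (0.033) and without sh830 (0.00092).

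**Figure D5:**
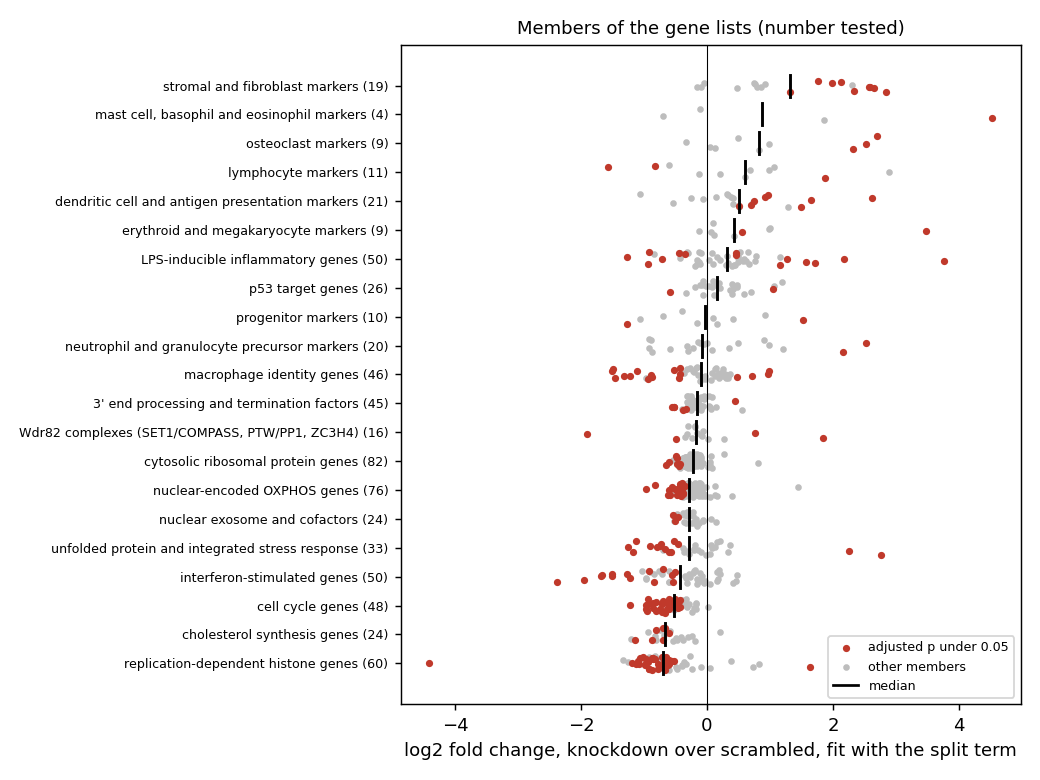
Each point is a gene of a list fixed beforehand, placed by its log2 fold change (knockdown over scrambled) in the fit with the library term; red points passed at an adjusted p under 0.05 and black bars are medians. Medians run from 1.32 for stromal markers to -0.69 for histone genes, and cell cycle genes lie almost all below 0.

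Intron counts can hold reads of unspliced RNA and of other transcripts that overlap an intron, whose shares were not tested. They were compared in the same way as exon counts. Of 12405 genes tested, 740 rose and 488 fell with the library term. Asgr2 rose by 5.14 ± 0.39 log2 units, from 0.310 ± 0.081 to 9.93 ± 1.8 CPM, and Cd300c by 4.70 ± 0.42, from 0.270 ± 0.036 to 7.12 ± 1.2 CPM. Ncam2, a neural cell adhesion gene, rose by 4.62 ± 0.37, from 0.768 ± 0.048 to 17.0 ± 13.0 CPM.

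All 8 named intron rises started from few counts. In scrambled 1 and 2, Asgr2 had 6 and 3 intron counts, Cd300c 7 and 2, and Ncam2 19 and 6. The integrin gene Itgad had 1 and 0 counts in the scrambled libraries and 69 and 17 with sh1137 and sh830, a ratio of 82.6 (exact 95% binomial interval 14.4 to 3299), with Cox6a2 in its span. Gene 414102, which has no symbol in the table used and overlaps Ccl6, had 0 counts in both scrambled libraries and 32 and 37 in the knockdown, at least 22.1-fold higher. The serpin gene Serpinb2 had 6 and 0 counts against 133 and 60, the actin gene Acta1 4 and 0 against 122 and 8, and AU019990 4 and 0 against 77 and 33. Camk2b fell by 2.08 ± 0.25, from 5555 ± 100.0 to 1399 ± 685 CPM (scaled to intron counts; the source of so many intron counts was not tested). Oas1g (-2.14), Oasl1 (-1.99), Ifi27l2a (-1.96), Mx1 (-1.87) and Oas2 (-1.65), all interferon-stimulated, fell, and so did Fcgr1 (-1.64) and the lymphocyte receptor gene Cd72 (-1.45; Tesk1 overlaps it). Adjusted p-values for the 16 genes lay between 0.0017 and 0.022 in edgeR.

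Among intron counts, camera called 3 lists higher and 7 lower. Lower were the lists of the cell cycle (19 of 47 members fell, adjusted p = 2.1e-16 in camera), interferon-stimulated genes (13 of 42, 1.4e-10), cytosolic ribosomal proteins (9 of 78, 3.5e-06), the stress response (8 of 31, with 1 that rose, 0.00080), the nuclear exosome (1 of 23, 0.0054), cholesterol synthesis (0 of 24, with 1 that rose, 0.0057) and macrophage identity (8 of 43, with 3 that rose, 0.028). The macrophage list did not pass in camera with the library term (adjusted p = 0.064), and the other lists did. Higher were the lists of osteoclast (3 of 7, 0.020), stromal (2 of 10, 0.027) and dendritic markers (1 of 11, 0.034). Of all these lists, only those of the cell cycle and of interferon-stimulated genes kept their call in camera whichever library was left out. With an estimated correlation none passed: the adjusted p was 0.21 for the cell cycle and ran from 0.64 to 0.79 for the others. Without scrambled 1, scrambled 2, sh1137 or sh830 camera called 0, 3, 5 and 2 intron lists higher and 11, 2, 2 and 9 lower. The ribosomal list turned higher without sh1137 (adjusted p = 0.044) and the stromal list lower without scrambled 1 (0.25). With the group term alone edgeR called 0 of 12405 genes, with 566 higher and 142 lower at an unadjusted p under 0.05. DESeq2 called 158 higher and 8 lower, and edgeR without the count filter 60 and 3. Scaling intron counts by the exon factors moved the median of all genes by 0.11 log2 units and changed the calls with the library term to 1530 higher and 355 lower, 81.2% higher in place of 60.3%. Without scrambled 1, scrambled 2, sh1137 or sh830 the fit with the group term called 121, 5, 211 and 175 genes higher and 9, 0, 24 and 42 lower.

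Intron against exon change asks whether the intron and exon counts of a gene moved apart. Of 11772 genes, 258 moved up in introns relative to exons and 172 moved down with the library term. For the 12 named genes, the p-values of this fit followed a normal distribution of the difference over its standard error. The spread of each gene was thus in effect treated as known, with no allowance for error in its estimate. In simulated data 16.0% of the calls of this fit were false, so these counts are less certain than those for exons. Trpm1, a cation channel gene whose introns hold Mir211, had a difference of 4.38 ± 0.93 log2 units (intron 4.51, exon 0.22; adjusted p = 0.00036 in edgeR). Cbr2, a carbonyl reductase gene, had 3.24 ± 0.86, Acmsd 3.15 ± 0.88 and Gsg1 2.96 ± 0.89, with exon log2 fold changes of -0.39, -0.09 and -0.21. Lyz1 (4.30 ± 0.54) overlaps its near-identical neighbour Lyz2, and Itgad rested on 1 intron count in the scrambled libraries, so both are uncertain.

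In the other direction, Stum (-2.90 ± 0.70) rose by 3.21 in exons against 0.33 in introns. Tg, the thyroglobulin gene (-2.94 ± 0.60; Sla lies within it), Mef2b (-2.66 ± 0.63; overlapped by Borcs8) and Col1a1 (-2.68 ± 0.80, but 0.67 and not past the threshold without sh830) had the same pattern. Cd6 and Fcrla also passed (adjusted p = 0.043 and 0.00043 in edgeR), but with 0 and 1 exon counts in the scrambled libraries the size of their difference cannot be given. Without the library term, edgeR called 0 genes, with 49 higher and 19 lower at an unadjusted p under 0.05, and at most 3 when a library was left out. DESeq2 was not run on this term. With the exon factors for intron counts, 418 genes were higher and 47 lower, 89.9% higher in place of 60%.

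Gene length was compared because a change in termination can act by distance along a gene. Genes in the longest quartile by span had a median exon log2 fold change of 0.06 (camera p = 0.013; p = 0.39 with an estimated correlation) and those in the shortest -0.05 (p = 0.27). In introns the medians were 0.06 (camera p = 0.0043; p = 0.64 with an estimated correlation) and -0.03 (p = 0.36). The values for the longest quartile turned negative without sh1137 (-0.04 in exons, -0.20 in introns) and, in introns, without scrambled 2 (-0.10). Those for the shortest quartile turned positive without scrambled 2 (0.08 and 0.27) and, in introns, without sh1137 (0.21). Scrambled 1 minus scrambled 2 had medians of 0.20 in exons and 0.48 in introns for the longest quartile. For the shortest they were -0.15 and -0.52, so the scrambled libraries differed by more than the groups.

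The hairpins were compared across the 13884 genes, which are not independent replicates. Against the mean of the scrambled libraries, the changes with sh1137 and sh830 had a Pearson r of 0.22, a Spearman rho of 0.10 and a covariance of 0.137. Libraries simulated with no effect against shared controls gave r = 0.33 and a covariance of 0.197 (mean of 20 simulations). That simulation leaves out the split of the libraries, which by itself lowers this correlation, so the comparison with it does not tell whether the hairpins agree. With sh1137 against scrambled 1 and sh830 against scrambled 2, r was 0.63. With the scrambled libraries exchanged it was -0.34. Of all tested genes, 31.3% had both knockdown libraries on one side of both scrambled libraries, against 33.3% by chance for exchangeable libraries, which also leaves out the split.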

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

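The fits with the library term or the crossed term, all alternatives run within the former, and regions without exon overlap were chosen after seeing the data. The labels number the scrambled libraries but not the knockdown libraries, so no paired analysis was planned. With 1 library for each combination, the fit with the library term is the same as a paired one that puts scrambled 1 with sh1137 and scrambled 2 with sh830 (841 exon genes higher and 1081 lower), and the crossed term is the other pairing. Leaving out a library could not be combined with the library term. For the calls below the cause of a change was not tested, except that an estimated correlation widens the error of a list, a test against a fold of 1.5 asks for more, and regions without exon overlap are fewer. A lone library left in a group was assumed to vary like the other group.

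With the group term alone, exon genes passed 0 times in either direction in edgeR, but 153 (higher) and 23 (lower) times in DESeq2, 841 and 1081 times with the library term, and 23 and 1 times with the crossed term. Leaving out each library gave 13 to 190 higher and 1 to 28 lower. Introns gave 158 and 8 in DESeq2, 60 and 3 without a filter, 740 and 488 with the library term, 60 and 2 with the crossed term, and 5 to 211 and 0 to 42 on leaving out a library. Regions gave 283 in DESeq2, 584 with the library term, 67 with the crossed term and 23 to 364 on leaving out a library, all higher. Intron against exon gave 258 and 172 with the library term by interval type, and 0 to 3 and 0 on leaving out a library. The log2 fold change of Wdr82 passed in DESeq2 (-1.90) and with the library term (-1.91), and ran from -2.28 to -1.58 on leaving out a library.

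Within the library term, a test against a fold of 1.5 kept 170 higher and 51 lower exon genes, 190 and 16 intron genes and 280 regions. Regions without exon overlap came to 387. Intron genes came to 1233 and 1133 without a filter, 1530 higher with exon factors, 915 lower with DESeq2's size factors in edgeR and 318 lower in DESeq2. Intron against exon came to 418 and 47 with exon factors. Of exon calls, 1508 of 1511 genes called with DESeq2's size factors and 1503 of 1685 called by DESeq2 were among the 1922.

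The region classes no longer passed with an estimated correlation (p = 0.17 for all regions, 0.230 TES, 0.165 TSS, 0.189 intergenic, 0.206 overlapping, 0.180 near a start, 0.252 near an end) or in fry (0.191, 0.245, 0.155, 0.179, 0.199, 0.143 and 0.265 in the same order). They passed on leaving out any 1 library. Gene lists called higher (6 for exons, 3 for introns) and lower (9 and 7) all went to 0 with an estimated correlation or fry, with and without the library term. In simulated data genes were drawn independently and 1 list was moved. Its unadjusted p was 0.0039 with an estimated correlation and 0.0030 in fry with the group term alone. With the library term these were 0.042 and 0.043. The real lists were adjusted over all tested lists, and their genes need not be independent. The simulation therefore does not tell whether these tests could pass a real list here. Leaving out a library gave 5 to 7 exon lists higher and 5 to 9 lower, and 0 to 5 intron lists higher and 2 to 11 lower.

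Among results that had passed, these directions turned on leaving out a library, as ranges of the adjusted p: exon histones 1.1e-64 to 0.33, ribosomal proteins 2.4e-28 to 4.3e-05, OXPHOS 1.6e-20 to 0.11 and stromal markers 7.0e-23 to 0.74, and intron ribosomal proteins 1.6e-35 to 0.75 and stromal markers 3.8e-22 to 0.25. As ranges of the fitted log2 fold change they were H2bc23 -13.79 to 3.09, H4c3 -2.28 to 0.19, Rpl22l1 -1.44 to 0.27, Fscn1 -0.61 to 5.35, Col1a1 -2.61 to 8.08 and its intron against exon change -3.91 to 0.67. Gene length medians moved from -0.12 to 0.078 (shortest quartile) and -0.036 to 0.26 (longest) in exons and from -0.31 to 0.27 and -0.20 to 0.41 in introns, and summed exon length gave -0.12 for the shortest in exons, which then passed in camera at the preset correlation (p = 0.029). In camera at the preset correlation the shortest quartile also passed as lower without scrambled 1 (p = 0.0026 in exons, 1.9e-13 in introns) or sh830 (0.012 and 1.0e-07), and in introns as higher without scrambled 2 (0.0016) or sh1137 (4.2e-05). Lists that had not passed changed direction in another 23 values. They passed in that direction for the exon Menin/MLL complex without scrambled 2 and, in introns without scrambled 1, for LPS-inducible genes and p53 targets. Other intron lists passed without a change of direction. Small nucleolar RNA hosts and OXPHOS genes did so as lower without scrambled 1 or sh830. LPS-inducible genes did so as higher without scrambled 2 or sh1137, and p53 targets and lymphocyte markers as higher without sh1137. The correlation of the hairpins went from 0.22 to 0.63 with a scrambled library each along the split and to -0.34 across it.

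For single named features, chosen in the fit with the library term and refitted without it, 165 exon, 32 intron and 10 region values kept their side of the threshold on leaving out a library, while 201, 31 and 6 no longer passed. For intron against exon 2 values kept their side, 45 no longer passed and 1 turned. Another 5 exon values turned, 1 passed that had not, and 24 of members that had not passed changed direction. The lower depth of sh1137 in exons and of scrambled 2 and sh830 in introns limits features with few counts.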

Other observations

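The tests of the library term, of the authors' choice of regions and of neighbouring regions without exon overlap were chosen only after their results were seen. The other tests were set out before.

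Several genes of immunity, lipid handling and the amino acid response outside the naming rule, chosen after their values were seen, changed with the library term in edgeR. The complement genes C1qa (-1.11), C1qb (-1.46) and C1qc (-0.87) fell, as did the chemokine receptor gene Cx3cr1 (-1.49), the pore-forming gene Mpeg1 (-1.33) and the lipid-sensing nuclear receptor gene Pparg (-1.23). The integrin gene Itgax (0.96) and the cholesterol exporter gene Abca1 (0.48) rose. Among inflammatory genes, Ptgs2 (2.18), which encodes an inducible cyclooxygenase, Egr2 (1.72) and Cxcl1 (1.57) rose, and the chemokine gene Ccl2 (-0.94) and Fos (-0.92) fell. The class II genes H2-Eb1 (1.66), H2-Aa (0.70) and H2-Ab1 (0.51) rose. The amino acid response genes Chac1 (-1.26), Asns (-1.12) and Atf4 (-0.45) fell.

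Calls were many with the library term and 0 without it. The crossed term called 24 exon genes (23 higher and 1 lower) against 1922, so not every added term gives as many. That term leaves the split in the residual spread, so its few calls do not tell whether the library term gives too many. The scrambled difference and the hairpin difference correlated across genes (r = 0.80), which is consistent with a library difference shared by scrambled 1 with sh1137 and by scrambled 2 with sh830. Within each side of it the hairpins also changed genes alike (r = 0.63), so changes shared by both hairpins remain open together with it. The source of the library difference stays open, since the labels name no batch.

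Of 1070 non-gene regions tested, 584 rose with the library term, and 98.3% had a positive log2 fold change with the group term alone, which the authors' choice of regions from a knockdown comparison could produce, so a loss of early termination cannot be inferred from the direction alone. A uniform background of genomic DNA or unspliced RNA raised in the knockdown libraries would also raise introns of matched count density, and these had a mean over 20 classes of 0.21 in their median log2 change, with 0.87 in the sparsest class. A uniform background is therefore argued against for rises well beyond that size. The regions were chosen for a rise and the introns were not, so the gap from the median of the regions (1.37) does not exclude a background that differs by place. A rise of the genes the regions are named for is argued against as the source of most of it, since those genes had a median of 0.091 (120 rose and 61 fell of 794). It could still have a part, since the changes of regions and of their named genes correlated (r = 0.295) and 116 of the 584 regions that rose had a named gene that rose. What stays open is the choice of regions, a background that differs by place, a part of the named genes and an effect of Wdr82 loss, which these libraries cannot separate.

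The 841 genes that rose might come from stromal cells in the knockdown cultures, but the genes as a set did not follow the stromal markers between the scrambled libraries (median 0.026 for scrambled 1 minus scrambled 2, against -4.18 for the markers). An expressed gene upstream on the same strand within 20 kb was no more common for genes that rose (153 of 841) than for those not called (2452 of 11948). The Mantel-Haenszel odds ratio within classes of expression was 0.863 (95% interval 0.720 to 1.04), so such a neighbour did not set the genes that rose apart. The test asked only whether that gene was present, not whether its transcription ran on, so it does not decide on read-through. Read-through into some of them is not excluded, since RNA between each gene and its upstream neighbour was not examined, nor were distances beyond 20 kb. Transcription that enters from a region that rose within 5 kb stays open for some. Of 841 genes that rose, 103 had such a region, against 285 of 11948 not called. The Mantel-Haenszel odds ratio within classes of expression, which differs from the ratio of these pooled counts, was 7.12 (95% interval 5.56 to 9.11). The counts were 46 against 130 when regions that overlap an exon were left out (6.26, 4.40 to 8.89, by the same measure). Both intervals treat genes as independent, although neighbouring genes can share a region. Regions on either side of a gene or inside it were counted, without strand. These ratios therefore cannot tell entry into a gene from a region that rose with it. Such regions lie near 12.2% of the genes that rose, regions were chosen from a comparison of the same kind, and neighbours could share reads. No further explanation was tested, and an effect of Wdr82 loss on the genes that rose remains open.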
